A study of Rattus norvegicus with 3 samples.

How the data were processed

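Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on round spermatids of Sprague-Dawley rats. Round spermatids are the haploid germ cells that follow meiosis and have not yet elongated. Per the labels' protocols, nuclei were lysed by sonication, chromatin was precipitated with an antibody against H3K4me3 or H3K9me3, and the libraries were read as paired ends on an Illumina NextSeq 500. The 3 samples fell into 3 groups of 1 library each: the H3K4me3 precipitate, the H3K9me3 precipitate and a library made without antibody. A peak list was analysed for each of the 2 marks. No peaks of the library without antibody were analysed here. The naming of the lists pairs each mark with it, and it is taken here as the control of both lists, a reading that the labels do not state. The word negative in that naming is also in the title of the library without antibody, which favours the reading as its name. It could still stand for peaks called with control and precipitate exchanged, in which case all positions and overlaps would describe excess of the control. The peak lists alone do not exclude this second reading.

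Per the submitters' processing notes, bcl2fastq, FastQC, Bowtie 1.2 and the rat build rn6 were used, with no roles or order given. The mapping settings, the treatment of reads with several matching places, duplicate removal and the settings of the peak caller are not given in the sources used here. The peaks in both files carry names given by the caller MACS. Each row of the deposited lists holds a sequence name, a start, an end and the authors' score for that peak. No header states what the score is. Its lowest value was 30.0 in both lists, its highest was 3198 for H3K4me3 and 3217 for H3K9me3, and 20 and 100 peaks sat at exactly 3100. This resembles the output of early MACS versions, in which the score grows with the negative logarithm of the p-value, a reading inferred from the values. The score was used mainly to rank and filter peaks within a list, since it depends on library depth. Its means and medians are given as a description, and the copy number comparison for X assumes that it grows in proportion to depth. No peak overlapped another peak of its own list. Starts are given here counted from 1.

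The files hold no read counts, so the sequencing depth of the libraries is unknown, and no limit of detection could be given for a region without a peak. Each mark rests on 1 library. There is no replicate error, and no p-value was computed between the marks. Exact Poisson intervals of peak numbers and Wilson intervals of shares, both at the 95% level, treat peaks as independent and cover counting error only.

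Peaks on chromosomes 1 to 20, X and Y entered the comparisons. The span of a chromosome was taken as the largest peak end in either list, 2777 Mb in sum, because the rn6 sequence was not used here. For Y, whose last peak ended at 2.32 Mb, this span is a lower bound and densities were not compared. Covered length per chromosome was set against the median autosome. Overlap of at least 1 bp between marks was compared with 1000 placements of the H3K9me3 peaks at random positions on their own chromosome. The overlap in 10 classes of equal size by score used 200 such placements. Clustering was measured as the share of covered length in the densest 1% of 1-Mb windows on chromosomes 1 to 20 and X, again against 1000 placements. Distances between neighbouring peaks were set against 100 placements. Ranges of placements are the 2.5th to 97.5th percentiles and describe these lists, not animals. The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

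The overlap procedure was tested on simulated data. Of 7642 simulated H3K4me3 peaks, 0%, 10% and 30% were put on H3K9me3 peaks that had themselves been placed at random. After correction for the random overlap, -0.02%, 10.1% and 29.7% were recovered. This checks the calculation only, because the simulated peaks lacked the clustering of the real lists.

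The design, the alternatives and the rule for named regions were fixed before the data were examined. The rule names, per mark, the 10 peaks with the highest score (ties by width) and the 5 densest 1-Mb windows. Other regions named in the text were chosen after their values were seen. The alternatives were a score at or above the list median, overlap of 0.5 of the smaller peak, a distance of 1 kb, placement within the same 1-Mb window, leaving out X and Y, peak numbers in place of covered length, and 5-Mb windows. The H3K9me3 domains (at least 3 neighbouring 1-Mb windows, each over 5% covered), the outlines of the chromosome 13 domain and the settings that leave out the domain, its window from 33 to 34 Mb or the densest H3K4me3 windows were added after the data were seen.

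Promoters, gene lists and sequence composition had been planned for the case of an rn6 annotation. The gene table used here follows another assembly, GRCr8, whose coordinates cannot be set against rn6 peaks. No peak was therefore assigned to a gene. Only the number of genes per autosome was taken from that table, for protein-coding genes, zinc finger genes (symbols of the Zfp and Znf series) and olfactory and vomeronasal receptor genes, under the assumption that genes kept their chromosome between the assemblies. Their relations to peak density were tested with two-sided permutation tests of 100000 resamples, adjusted by Benjamini-Hochberg over 6 relations.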

Results

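H3K4me3, a histone mark typical of active promoters, and H3K9me3, a mark typical of heterochromatin, were mapped in rat round spermatids to ask where each lies in the genome of these cells and, as the title of the study states, how histone methylation relates to the genes they express. The H3K4me3 list held 7684 peaks over 8.70 Mb and the H3K9me3 list held 49591 peaks over 65.1 Mb. Each list comes from 1 library of unknown depth, so values below have no replicate error. The peaks are read as enrichment over the library without antibody, which the labels do not state.

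The H3K9me3 peaks covered 7.48 times the length of the H3K4me3 peaks and were 6.45 times as numerous. On the assembled chromosomes, H3K4me3 peaks covered 0.311% of the span and H3K9me3 peaks 2.33%. Single peaks of the marks were of like size. The median width was 889 bp for H3K4me3, with quartiles of 685 and 1303 bp, and 927 bp for H3K9me3, with quartiles of 684 and 1486 bp. Wide peaks were mostly H3K9me3, with 826 of 49591 peaks over 5 kb against 31 of 7684 for H3K4me3, so part of this contrast is list size. The mean score was 111 for H3K4me3 and 128 for H3K9me3, and 50.5% and 40.1% of the peaks had a score under 50. Scores and numbers of peaks depend on depth, and the ratio between the lists therefore does not measure how much of each mark the cells carried.

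H3K9me3 was concentrated on chromosome 13. Its peaks covered 11.6% of that chromosome, 6.69 times the median autosome, whereas the other autosomes ranged from 0.764% on chromosome 11 to 3.02% on chromosome 8. H3K4me3 on chromosome 13 lay at 0.761 times the median autosome. H3K4me3 was spread more evenly, from 0.194% on chromosome 11 to 0.464% on chromosome 1, with chromosomes 7 and 12 at 0.463% and 0.457%. Chromosome 11 had the lowest covered share of both marks among the autosomes.

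**Figure D1:**
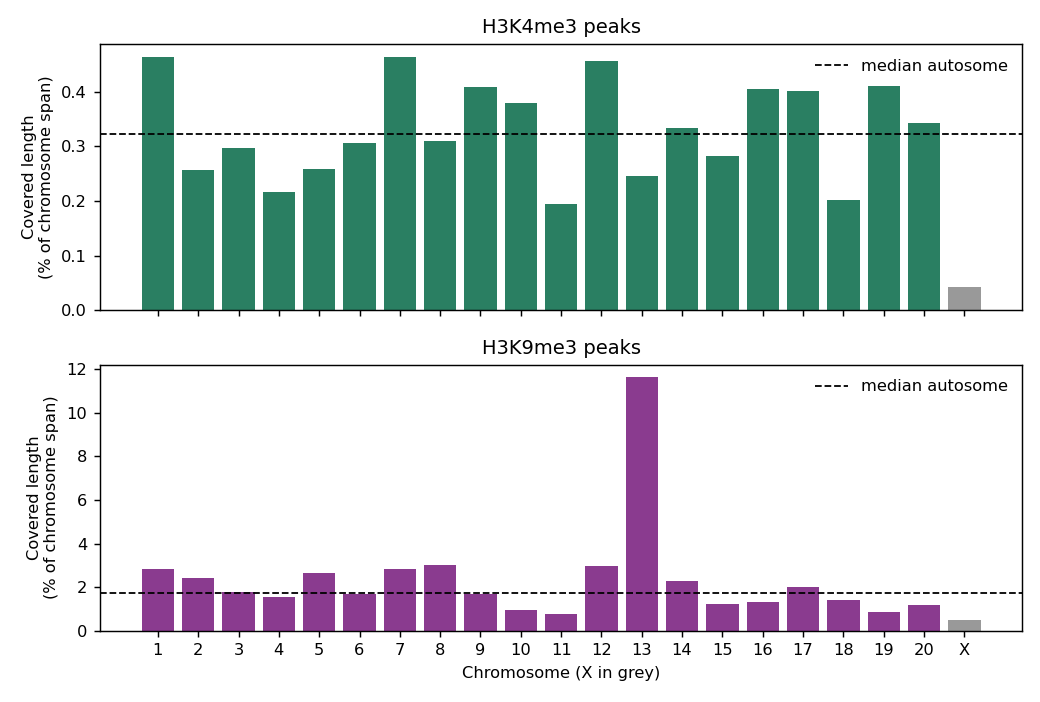
Covered length of H3K4me3 peaks (top) and H3K9me3 peaks (bottom) as a percentage of each chromosome's span, with 1 bar per chromosome from 1 library per mark and the median autosome as a dashed line. Chromosome 13 reaches 11.6% for H3K9me3, and X, in grey, lies below every autosome for both marks.

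The X chromosome carried few peaks of either mark for its length. The comparison of X with the autosomes was planned because the sex chromosomes of spermatids form a separate chromatin domain. H3K4me3 peaks covered 0.0428% of X, 0.133 times the median autosome, and numbered 68, or 0.425 per Mb (95% Poisson interval 0.330 to 0.539). The autosomes ranged from 1.79 to 4.10 H3K4me3 peaks per Mb. H3K9me3 peaks covered 0.498% of X, 0.286 times the median autosome, and numbered 917, or 5.73 per Mb (5.37 to 6.12), against 7.13 to 67.6 on the autosomes. X thus lay below the lowest autosome for both marks, in covered percentage and in peaks per Mb. The median H3K9me3 score was also lower on X, at 38.2, than on any autosome, where it ranged from 42.3 to 88.1. With only the peaks at or above the median score of the list, H3K9me3 on X was at 0.152 times the median autosome. The depth of the libraries on X is unknown, so peaks missing there may lie under the detection limit of the caller.

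On X, 49 of the 68 H3K4me3 peaks lay on an H3K9me3 peak (72.1%, Wilson interval 60.4 to 81.3%). The remaining 19 gave 0.119 peaks per Mb (0.0715 to 0.186), 0.0583 times the median autosome for H3K4me3 peaks off H3K9me3 and below the autosomal range of 1.42 to 2.98. The 49 on H3K9me3 gave 0.306 peaks per Mb (0.227 to 0.405), 0.379 times the median autosome and inside the autosomal range of 0.133 to 1.83 for that class. On Y, 2 H3K4me3 peaks were listed, at positions 1849889 to 1850996 with a score of 598 and 1851862 to 1853024 with a score of 1085. Both overlapped an H3K9me3 peak, and these carried the highest H3K9me3 scores on Y, 1701 and 2367.

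The H3K9me3 excess of chromosome 13 lay in its proximal part in rn6 coordinates. Between 1 and 35 Mb, 7330 peaks covered 38.0% of the sequence, or 21.8 times the median autosome. This region held 19.99% of the H3K9me3 covered length on chromosomes. Of its 34 windows of 1 Mb, 30 exceeded the 95th percentile of windows on the other autosomes, which was 112 kb. The windows ranged from 5.88 to 650 kb with a median of 421 kb. The remainder of chromosome 13 was covered to 0.419%, or 0.241 times the median autosome, for which the other autosomes kept all their peaks. The 5 densest H3K9me3 windows of the genome, at 3 to 4, 7 to 8, 8 to 9, 11 to 12 and 20 to 21 Mb of chromosome 13, were covered by 650, 582, 641, 624 and 606 kb, and none of these 5 held an H3K4me3 peak. Peaks in the region had a median width of 1276 bp and a median score of 93.1. H3K4me3 listed 60 peaks there, 0.605 times the peak density of the median autosome (0.462 to 0.779). Of these, 35 fell in the window from 33 to 34 Mb, and all 35 lay on an H3K9me3 peak. Without that window the density was 0.260 times the median autosome (0.168 to 0.383).

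**Figure D2:**
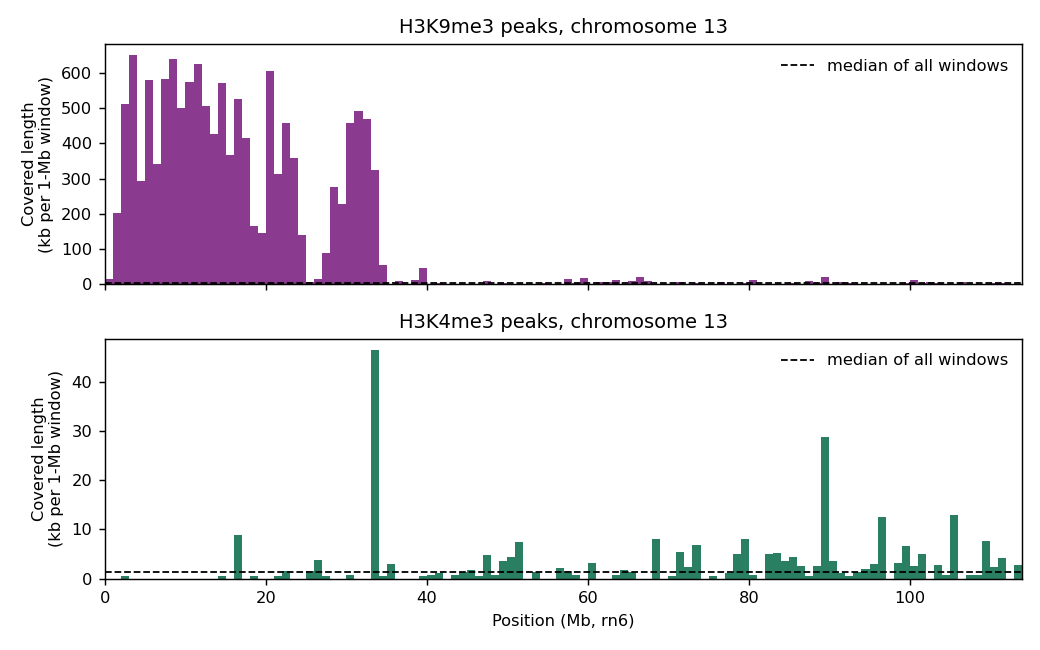
Covered length in kb per 1-Mb window along chromosome 13 (rn6) for H3K9me3 (top) and H3K4me3 (bottom), 1 library per mark, with the median of all windows as a dashed line. H3K9me3 windows between 1 and 35 Mb reach up to 650 kb, while most H3K4me3 covered length in that region lies in the window from 33 to 34 Mb.

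Chromosome 13 was the extreme of a wider pattern. H3K9me3 peaks formed 29 domains, defined as runs of at least 3 windows with over 5% covered, on 15 chromosomes. They spanned 146 Mb and held 50.7% of the H3K9me3 covered length on chromosomes. These totals include the domains of chromosome 13, which held 10498 and 2388 kb of the 64.6 Mb covered on chromosomes. The largest by covered length were 1 to 25 Mb and 27 to 35 Mb of chromosome 13, covered to 43.7% and 29.8%. Outside chromosome 13, the region from 0 to 11 Mb of chromosome 7 was covered to 16.6%, that from 73 to 78 Mb of chromosome 1 to 31.3%, that from 16 to 22 Mb of chromosome 8 to 25.9%, and that from 46 to 52 Mb of chromosome 14 to 19.99%. No domain was found on X, nor on chromosomes 10, 11, 16, 18 and 20. With a minimum of 10% covered per window, 17 domains remained on 11 chromosomes, with 41.2% of the covered length, chromosome 13 included. H3K4me3 cover in these domains differed widely. Among the 29 domains it ran from 0.0166% between 10 and 14 Mb of chromosome 5 to 2.055% between 26 and 29 Mb of chromosome 19.

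Both marks were clustered. The densest 1% of windows, 28 of 2786, held 21.1% of the H3K9me3 covered length, against 5.82% (5.68 to 5.96%) when the peaks were placed at random. For H3K4me3 they held 16.2%, against 4.37% (4.11 to 4.62%). No H3K9me3 peak lay in 326 windows, 11.7% of all, against 0.0721% at random, and no H3K4me3 peak in 741 windows, 26.6%, against 10.4%. The median distance between neighbouring peaks was 1.78 kb for H3K9me3, against 31.7 kb at random, and 80.6 kb for H3K4me3, against 231 kb. All of these observed values lay outside the ranges of the placements. With 5-Mb windows, the densest 1% held 7.82% of the H3K4me3 covered length, against 2.79% at random. Assembly gaps and unmappable sequence were not excluded from the placements.

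The densest H3K4me3 windows were also rich in H3K9me3. The window from 55 to 56 Mb of chromosome 1 held 67 H3K4me3 peaks over 103 kb, followed by 12 to 13 Mb of chromosome 9 with 66 peaks over 84.9 kb, 8 to 9 Mb of chromosome 9 with 64 peaks over 70.02 kb, 54 to 55 Mb of chromosome 1 with 44 peaks over 65.1 kb and 5 to 6 Mb of chromosome 15 with 59 peaks over 64.7 kb. H3K9me3 peaks covered 159, 137, 207, 74.1 and 118 kb of these 5 windows, against a median of 3.74 kb over all windows, and the windows ranked 106, 124, 75, 213 and 148 of 2786 for H3K9me3. None was among the 28 densest H3K9me3 windows, of which 19 lay on chromosome 13. Over all 2786 windows the rank correlation of the covered lengths was near 0 (Spearman's rho -0.0011 across windows of the same 2 libraries, no p-value, as neighbouring windows are not independent). It weights all windows alike and does not reflect the windows with most H3K4me3.

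At the scale of peaks, the marks coincided. Of the 7642 H3K4me3 peaks on chromosomes, 2439 overlapped an H3K9me3 peak (31.9%, Wilson interval 30.9 to 32.97%). Random placement of the H3K9me3 peaks gave 324 (286 to 359), so the overlap was 7.53 times as frequent as at random. Placement within the same 1-Mb window gave 534 (494 to 580) and a ratio of 4.56. The ratio was 4.47 for peaks within 1 kb of each other and 13.1 among peaks at or above the median score of their lists. Only 4.44% of the H3K9me3 peaks, 2177 of 49081, lay on an H3K4me3 peak. Both lists are taken to share the library without antibody as control, and part of the excess may come from it. Its share could not be simulated from peak lists.

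The coincidence rose with the score. It was 14.4% (12.1 to 17.0%) in the lowest of 10 score classes of H3K4me3 peaks and 59.9% (56.4 to 63.4%) in the highest, where random placement gave 3.43% and 6.83%. In the H3K9me3 list it was 0.856% (0.634 to 1.15%) in the lowest and 23.8% (22.7 to 25.1%) in the highest class, against 0.483% and 1.12% at random. Peaks were wider in the higher classes, with medians of 630 and 2289 bp in the lowest and highest class for H3K4me3 and 616 and 3313 bp for H3K9me3, which the placements take into account. H3K4me3 peaks on H3K9me3 had a median score of 68.1 and a median width of 890 bp, and those off it 43.6 and 888 bp. In the 28 densest H3K4me3 windows, 1022 of 1146 H3K4me3 peaks lay on H3K9me3 (89.2%, 87.2 to 90.8%), against 1417 of 6496 elsewhere (21.8%, 20.8 to 22.8%). Against placement within the same 1-Mb window, the ratio was 4.56 over all peaks and 4.93 outside the densest windows. The higher share in the densest windows is thus not a larger excess over local placement.

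**Figure D3:**
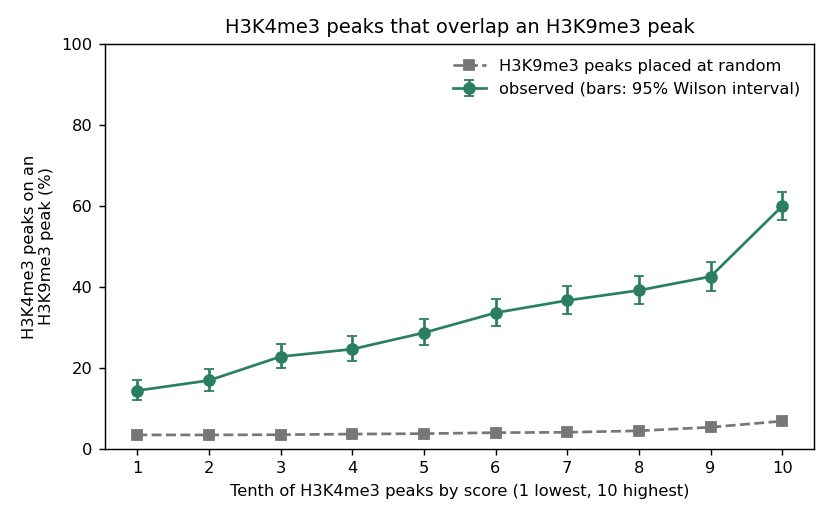
Percentage of H3K4me3 peaks that overlap an H3K9me3 peak, in 10 classes of equal size by H3K4me3 score (1 lowest, 10 highest), with 95% Wilson intervals as bars and the mean of 200 random placements as squares. The observed share runs from 14.4% to 59.9%, against 3.43% to 6.83% at random.

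Each of the 10 H3K4me3 peaks with the highest scores overlapped an H3K9me3 peak that had a score of 3100. The highest, at 181286387 to 181287214 of chromosome 1, had a score of 3198, and the next, at 181166447 to 181173113, had 3196. The other 8 had 3100. The widest of these ran from 228994956 to 229025974 of chromosome 1 over 31019 bp, and 5 lay between 55682002 and 56032608 of the same chromosome. The remaining ones were at 181071993 to 181079843 of chromosome 1 and 3350075 to 3357872 of chromosome 12. All 22 H3K4me3 peaks with a score of at least 3100 lay on H3K9me3.

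The 10 H3K9me3 peaks with the highest scores also all overlapped H3K4me3 peaks, whose best scores ran from 66.7 to 2595. The highest H3K9me3 score, 3217, was at 33474734 to 33479730 of chromosome 13, followed by 3215 at 100303066 to 100305529 of chromosome 7 and 3206 at 195107765 to 195110915 of chromosome 2. The next were 3204 at 36468994 to 36475067 of X, 3175 at 55648780 to 55652143 of chromosome 1 and 3167 at 15486122 to 15492954 of chromosome 14. Among those at 3100, the widest were 32775 and 24576 bp on chromosome 7, from 19728210 and 19660620, and 26261 and 25365 bp on chromosome 3, from 173090725 and 143887862. The wide peak at 19728210 of chromosome 7 overlapped 12 H3K4me3 peaks.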

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

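The tests of crowded regions, of the chromosome 13 domain and of X were chosen after the results were seen. The relation between the scores of overlapping peaks was set down before it was computed.

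Chromosome 13 was singled out because covered length was 6.69 times the median autosome for H3K9me3 and 0.761 times for H3K4me3. This difference was not tested, as each mark has 1 library. Low coverage of the domain between 1 and 35 Mb in the shared control, or extra copies of it, should raise H3K4me3 peaks there too, if the lists share that control. Their density was 0.605 times the median autosome (0.462 to 0.779), or 0.260 times (0.168 to 0.383) without the window from 33 to 34 Mb. In peaks per Mb, the domain stood at 0.814 times the rest of chromosome 13 for H3K4me3 and at 47.7 times for H3K9me3. No rise of all H3K4me3 peaks together was thus seen. The number to be expected there without such a cause is unknown, because the gene content of the domain was not available. As 52 of the 60 peaks also lay on H3K9me3, these values do not decide whether this cause contributed. A fault of the H3K9me3 library alone stays open, and no biological explanation was tested.

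H3K4me3 peaks lay on H3K9me3 peaks 7.53 times as often as at random. A few crowded regions were not the whole cause: outside the 28 densest H3K4me3 windows the overlap was still 4.93 times that of placements within the same 1-Mb window, 1417 peaks against 288 (259 to 321). Sequence that is over-represented in both precipitates, such as repeats collapsed in the assembly or regions poorly covered in the shared control, is a candidate explanation, since it predicts that the scores of a pair rise together, and over 2563 overlapping pairs Spearman's rho was 0.313 (bootstrap interval 0.272 to 0.349). Chromatin that carries both marks, in the same or in different cells, would give the same sign and stays open and untested.

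The low number of peaks on X may come in part from copy number, since a spermatid population holds fewer X chromosomes than sets of autosomes. If the score grows in proportion to depth, X peaks at a score of at least 30 should be as dense as autosomal peaks at a score of at least 60. For H3K9me3 the density on X was 0.836 times the median autosome and above 8 of the 20 autosomes. Copy number could give this density, but the scores on X were lower than it predicts from the whole list. The list median was 60.4 and the upper quartile 121, so peaks of the list at a score of at least 60 had a median near 121. Scaled as 60 to 30, X peaks should then have a median near 60, but theirs was 38.2. The list includes the chromosome 13 domain, which held 14.9% of the peaks on chromosomes with a median score of 93.1. A median of autosomal peaks at a score of at least 60 without that domain was not computed. These values therefore do not decide whether copy number alone explains H3K9me3 on X, even if the score scales in this way. For H3K4me3 the density ratio was 0.424, below all 20 autosomes. The interval on X, 0.330 to 0.539 per Mb, still met that of the lowest autosome, chromosome 11. That autosome stood at 0.542 per Mb with a lower bound of 0.401. The median H3K4me3 score on X, 59.0, was not below that of the autosomes. This comparison pooled H3K4me3 peaks on and off H3K9me3. Among all listed peaks, those off H3K9me3 were at 0.0583 times the median autosome on X and those on it at 0.379 times. The density at a score of at least 60 was not computed for each class. Copy number, the lower activity of the sex chromosomes in spermatids and the gene content of X cannot be told apart for H3K4me3, because the depth on X is unknown.

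Outside the chromosomes compared, mitochondrial DNA, which is not packed in histones, carried 5 H3K4me3 peaks and no H3K9me3 peak. They covered 5884 bp with scores from 36.5 to 107, where the upper quartile of the H3K4me3 list was 91.6. The H3K4me3 list thus holds some signal that is not the mark on that DNA. How much of such signal lies on the chromosomes is unknown. Sequences not placed on a chromosome carried 37 H3K4me3 peaks over 49.5 kb and 510 H3K9me3 peaks over 564 kb, which is 0.482% and 1.03% of the lists.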

How the results depend on the processing

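The settings without the chromosome 13 domain, its window from 33 to 34 Mb or the densest H3K4me3 windows and the 10% minimum were chosen after the results were seen. Of 37 recomputed values for 13 results, 14 stayed within the counting interval or, for counts and the ratio of covered lengths, within 1.5 times, 22 moved by more and 1 reversed. The reversal was H3K9me3 on chromosome 13, which fell to 0.241 times the median autosome without its domain. A fall was bound to follow, because the domain was outlined from the same values. The other autosomes kept their own domains in this comparison. Keeping peaks at or above the median score left 3842 H3K4me3 and 24804 H3K9me3 peaks by construction. It moved H3K9me3 to 0.152 times the median autosome on X and to 8.15 times on chromosome 13. It also raised the share of H3K4me3 peaks on H3K9me3 to 39.4%, the ratio to random placement to 13.1, and the share in the densest windows to 20.6% for H3K4me3 and 25.5% for H3K9me3. By number of peaks, H3K9me3 was at 0.400 times the median autosome on X and 4.72 times on chromosome 13. The overlap ratio was 11.01 with an overlap of 0.5 of the smaller peak, 4.56 with placement within the same 1-Mb window, and 4.47 for peaks within 1 kb, where the share was 33.7%. Without the densest H3K4me3 windows the share was 21.8% and the ratio, within the same 1-Mb window, 4.93. Without the chromosome 13 domain the ratio was 8.41 and the densest windows held 18.4% of the H3K9me3 covered length. Without the window from 33 to 34 Mb, H3K4me3 peaks in that domain were at 0.260 times the density of the median autosome. With 5-Mb windows, the densest 1% held 7.82% for H3K4me3 and 19.1% for H3K9me3. A minimum of 10% covered left 17 H3K9me3 domains. Apart from the reversal, no ratio crossed 1. Beyond the removal of peaks or windows, the cause of these moves was not tested. Alternatives that need rn6 sequence or genes (promoter windows, transcript starts, gene lists, sequence composition, spans without unknown bases) were not run. Depth is unknown, so a region without a peak cannot be told from one sequenced too thinly. No paired analysis was possible because each group has 1 library.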

Other observations

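The tests in this part were set down before they were computed, except the difference between the 2 classes of H3K4me3 peaks and the values without chromosome 13. H3K4me3 peaks were denser on autosomes with more protein-coding genes per Mb. This is a hypothesis tested on numbers of genes per chromosome from assembly GRCr8 over 20 autosomes, which are parts of 1 library per mark and not independent replicates. Between H3K4me3 peaks and protein-coding genes per Mb, Spearman's rho was 0.650 (permutation p = 0.00245, adjusted 0.00735 over 6 relations) and Pearson's r was 0.582 (permutation p = 0.0068, adjusted 0.0204). Without the 2 chromosomes farthest from the median gene density, r was 0.611. For the H3K4me3 peaks off H3K9me3, rho was 0.805 (permutation p = 6e-05, adjusted 0.00036) and r was 0.845 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted 6e-05), or 0.797 without those 2 chromosomes. For the H3K4me3 peaks on H3K9me3, rho was 0.185 (permutation p = 0.434, adjusted 0.759) and r was 0.190 (permutation p = 0.426, adjusted 0.639), or 0.341 without those 2 chromosomes. The difference between these rho values, 0.620, had a bootstrap interval from -0.0395 to 1.19, so the classes are not shown to differ in this relation. The peaks off H3K9me3 may lie mostly near genes, which peak positions set against rn6 genes would test. The relation of 0.805 is what promoter enrichment would give, but it was not tested whether lists with control and precipitate exchanged would lack it.

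H3K9me3 peak density was not shown to follow gene density. Spearman's rho was -0.0722 with protein-coding genes, 0.113 with 320 zinc finger genes, a class that carries H3K9me3 in other cell types, and 0.134 with 1434 olfactory and vomeronasal receptor genes. The permutation p values were 0.759, 0.635 and 0.570, and each was 0.759 after adjustment. Pearson's r was -0.225, -0.0988 and -0.0837, with permutation p values of 0.329, 0.673 and 0.764 and adjusted values of 0.639, 0.764 and 0.764. Without the 2 chromosomes farthest from the median gene density, r was -0.0706, -0.291 and -0.103. Without chromosome 13, which holds the large domain, rho was 0.0719, 0.298 and 0.160, and r was -0.0324, 0.344 and 0.0629.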
